A study of Mus musculus with 103 samples.

How the data were processed

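Single cells of mouse forelimbs were profiled by MARS-seq in 103 libraries, each 1 plate of 384 wells. The deposited values are raw UMI counts per gene and well, 1 table per library, with no normalization applied. Per the submitters' processing notes reads were demultiplexed with bcl2fastq 2.15.0.4 and the genome build was mm10, and the aligner and the gene models are not given in the sources used here. Per the labels' protocols the libraries read 3' ends of mRNA, limbs were digested with trypsin at E10.5 and E11.5 and with collagenase from E12.5 on, and cells were sorted by flow cytometry. Per the series' design text the forelimbs of a litter were pooled into 1 biological replicate. A deposited table of wells gives the authors' counts of cells sorted per well for 95 libraries, and the other 8 libraries are not in it. Its gene numbers equalled those of the UMI tables in 100% of listed wells. Its column of totals was taken as reads, with a median of 17.0 per UMI. The labels describe 2 read formats, and 20 libraries carried the earlier one, in which cell and molecule barcodes came from a separate read. These were the unsorted E10.5 libraries and those of 4 litters at E11.5 and E13.5.

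Libraries were grouped by the stage, gate and region in their labels. The 71 gated libraries of E11.5 to E14.5 came from 18 litters, and the replicate number of the labels was taken as the litter. Numbers with decimals, such as 18.1 and 18.2 or 20.1 and 20.2, were counted as litters of their own by assumption. If equal whole numbers share a litter, the 4 libraries of each E12.5 group come from 2 litters. Libraries 21.1 and 21.2 of each E13.5 group would then share a litter too. The 22 dissected E12.5 libraries came from 5 embryos of 2 litters, with the left and right limb of an embryo summed where both were sorted. The 4 unsorted E10.5 libraries, 2 plates each of replicates 7 and 10, entered no comparison. Each of the 3 libraries per E10.5 gate entered as a sample, although replicate number 22 appears on 2 plates of each gate, so these may share animals and the E10.5 p-values may be too small.

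The 92 spike-in sequences took 1.36% of all UMIs and were left out, which left 52542 genes. A well counted as a cell with at least 500 UMIs, at most 20% of them mitochondrial, and not recorded as empty. Of 39552 wells, 36229 reached the UMI minimum, and the mitochondrial limit removed 7868 of these (21.7%, from 0.741% to 68.4% per library). Among 380 wells recorded as empty the median was 18 UMIs, and 4 reached the minimum and were left out. Single-cell sorting stood in for a doublet caller, which was not run. Cells were log-normalized and clustered on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), which gave 22 clusters, against 38 at resolution 2. A cluster was named only if at least 3 markers of a fixed list were among its top 10 genes. Muscle-like (1275 cells), endothelial-like (125), erythroid-like (206), macrophage-like (226), ectoderm-like (335) and Schwann-like cells (133) were set apart, and all others were called mesenchymal, unnamed clusters included. These names rest on the rebuilt clusters, not on annotation by the authors.

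UMIs of the mesenchymal cells were summed per library, no library having fewer than 20 such cells. The sums were tested with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F test) in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05, two-sided. The 71 gated libraries were fitted together with a mean for each of 16 groups and no litter term, and gate comparisons averaged the 4 stages. The dissected limbs were fitted with the embryo as a block, and E10.5 by gate alone. Folds are log2 ratios of CPM, shrunken by edgeR's prior count for genes with few UMIs. Genes without a UMI on 1 side are given against a floor of 3 counts over the group, and floors and intervals cover counting error only.

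Fixed gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 and at an estimated correlation, and with fry, adjusted over the lists of each comparison. The 21 lists were limb progenitor, FGF response, hedgehog response, chondrocyte, growth plate hypertrophy, osteoblast and perichondrium, tendon, joint interzone, connective tissue fibroblast, proximal limb, autopod, BMP pathway, cell cycle, dissociation stress, muscle, endothelial, erythroid, macrophage and leukocyte, ectoderm, neural crest and Schwann cell, and pericyte and smooth muscle. Members are shared between some lists, such as Osr1 and Lum. The list members Lect1 and Snorc have no row in the tables under those names. Of 233 list tests 29 had a median, a mean and a camera direction of differing sign, and the 2 of these past the threshold are given with their values.

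Shares of cells with a UMI were taken after drawing 1000 UMIs from each cell without replacement, leaving out shallower cells. Stage differences were tested by exact permutation of libraries, the gate difference by 100000 permutations within stages, and the regional difference by exact sign flips of embryos. Codetection was the log odds ratio per library, with 0.5 added to each cell of the table, tested by sign flips and adjusted over 9 tests. Binomial intervals are exact (95%). Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and gene positions came from GENCODE M21.

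The genes named follow a rule: Sox9, Scx and Msx1 first, then the 10 largest increases and 10 largest decreases among genes at an adjusted p under 0.05 with an average log2 CPM of at least 5, then up to 4 members of each list in its direction with the smallest adjusted p, and the member called in the opposite direction with the smallest. For length the text gives part of the genes the rule names. Comparisons, their tests, the lists, the rule and all alternatives except those called added were chosen before the data were examined, while some tests of technical explanations and the splits of samples were chosen after.

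Libraries of a litter deviated together: over 5712 genes the mean correlation of deviations from group means was 0.283 within and -0.130 between litters, the lowest litter mean was 0.142, and 69 of 71 libraries matched best with their own litter. Dissected samples of an embryo had a mean of 0.158 (lowest 0.0378) against -0.0914 between embryos. The numbers were therefore read as litters, but the main fits of gated cells and the gate test of shares did not pair libraries by litter. Litters mostly lay within a sequencing batch: 63 of the 71 libraries have a recorded batch, and 2 of their 16 litters were spread over more than 1 of 12 batches, while 6 batches held more than 1 litter and 3 more than 1 stage. No 2 libraries of a group were the same library under 2 labels: over 187 pairs the chi-square per degree of freedom was 2.03 or more, against about 1 for resampled counts.

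The fits were tested on simulated counts with 200 changed genes. For the tomato-only comparison 78% of 2-fold and 100% of 4-fold changes were recovered, for the stage change of double-negative cells 30% and 68%, for E10.5 42% and 87%, and for the tomato+ region comparison 64% and 97%, with 5.32%, 3.92%, 8.51% and 6.40% false among the calls. Simulated codetection of -1 was returned as -0.901 and a simulated share difference of 20 points as 19.3. The simulated genes were found in many cells, with many UMIs in each, and the simulated shares were not thinned. Neither run therefore tests a gene as sparse as Msx1 in the GFP+ gates. Alternatives were DESeq2 1.42.0 as test or for size factors, no filter on low counts, 300 or 1000 UMIs per cell, the finer clusters, all cells, only the groups compared, the later read format, E12.5 for E11.5, the litter or embryo block, left limbs, embryo names, other thinning depths, and each replicate left out. Both added ones, without the mitochondrial limit and without a cluster led by S100a8, were chosen after seeing the data.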

Results

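Mouse forelimb cells were sorted one by one into 384-well plates between embryonic day (E) 10.5 and E14.5 and sequenced by MARS-seq, a 3' end protocol that counts mRNA molecules by unique molecular identifiers (UMIs). In 71 libraries the embryos carried a tamoxifen-inducible Sox9-CreER allele with a tdTomato reporter together with an Scx-GFP transgene. Sox9 is the transcription factor required for cartilage, so tomato marks cells with Sox9 activity around the tamoxifen dose, given 48 h before harvest, and their descendants. Scx is a transcription factor of tendon progenitors. The 4 gates are here called double-negative (GFP-tomato-), tomato-only (GFP-tomato+), GFP-only (GFP+tomato-) and double-positive (GFP+tomato+). They were sampled at E11.5, E12.5, E13.5 and E14.5 in 18 litters, which gave 16 groups of 3 to 5 libraries, 1 library per litter and gate. Each replicate number was taken as a litter, decimals such as 20.1 and 20.2 included. If such decimals shared a litter the E12.5 and E13.5 groups would hold fewer litters than libraries. A further 6 libraries held E10.5 cells sorted on a Sox9-GFP reporter (3 positive, 3 negative), and 4 held unsorted E10.5 cells. Another 22 held tomato+ or tomato- cells of the E12.5 autopod, the future hand, or of the proximal remainder of the limb, from 5 embryos. These embryos were of another line, listed as Sox9-CreTomato, and their cells were sorted on tomato alone. Their tomato gates are thus not split by Scx-GFP and are not the gates of the 71 libraries. The series title places Msx1-positive naive progenitors at the origin of the skeleton, so Sox9, Scx and Msx1 are given first in each comparison.

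Each of the 103 libraries held between 316804 and 2209078 UMIs, and 28361 cells passed the filters, with a median of 2058 UMIs and 1026 genes per cell. Of these cells 26061 were mesenchymal, and their UMIs were summed per library (248212 to 1770850 UMIs, from 113 to 360 cells) for all tests between groups. The 4 genes followed throughout are protein-coding, with positions on the mm10 assembly from GENCODE M21 gene models. Sox9 lies on chromosome 11 (112782224 to 112787760, plus strand) and Scx on chromosome 15 (76457452 to 76459458, plus strand). Msx1 lies on chromosome 5 (37820485 to 37824583, minus strand) and Col2a1 on chromosome 15 (97975602 to 98004695, minus strand).

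The gates were first set against the genes whose reporters define them. At E14.5 Sox9 stood at 816 ± 193 CPM (UMI counts scaled to an equal library total, mean ± SD, n = 5 libraries) in tomato-only and 165 ± 105 CPM in double-negative cells. Scx stood at 992 ± 73.3 CPM in GFP-only, 562 ± 106 CPM in double-positive and 32.8 ± 8.99 CPM in double-negative cells. Msx1 was highest in the double-negative gate at every stage (967 ± 142 CPM at E12.5, n = 4) and lowest in the double-positive gate (10.3 ± 3.29 CPM). The sort selects on labels tied to these genes, GFP to Scx and tomato to Sox9 activity around the tamoxifen dose. Sox9 between tomato gates and Scx between GFP gates therefore largely describe the sort, although tomato is kept whether or not Sox9 is still expressed.

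**Figure D1:**
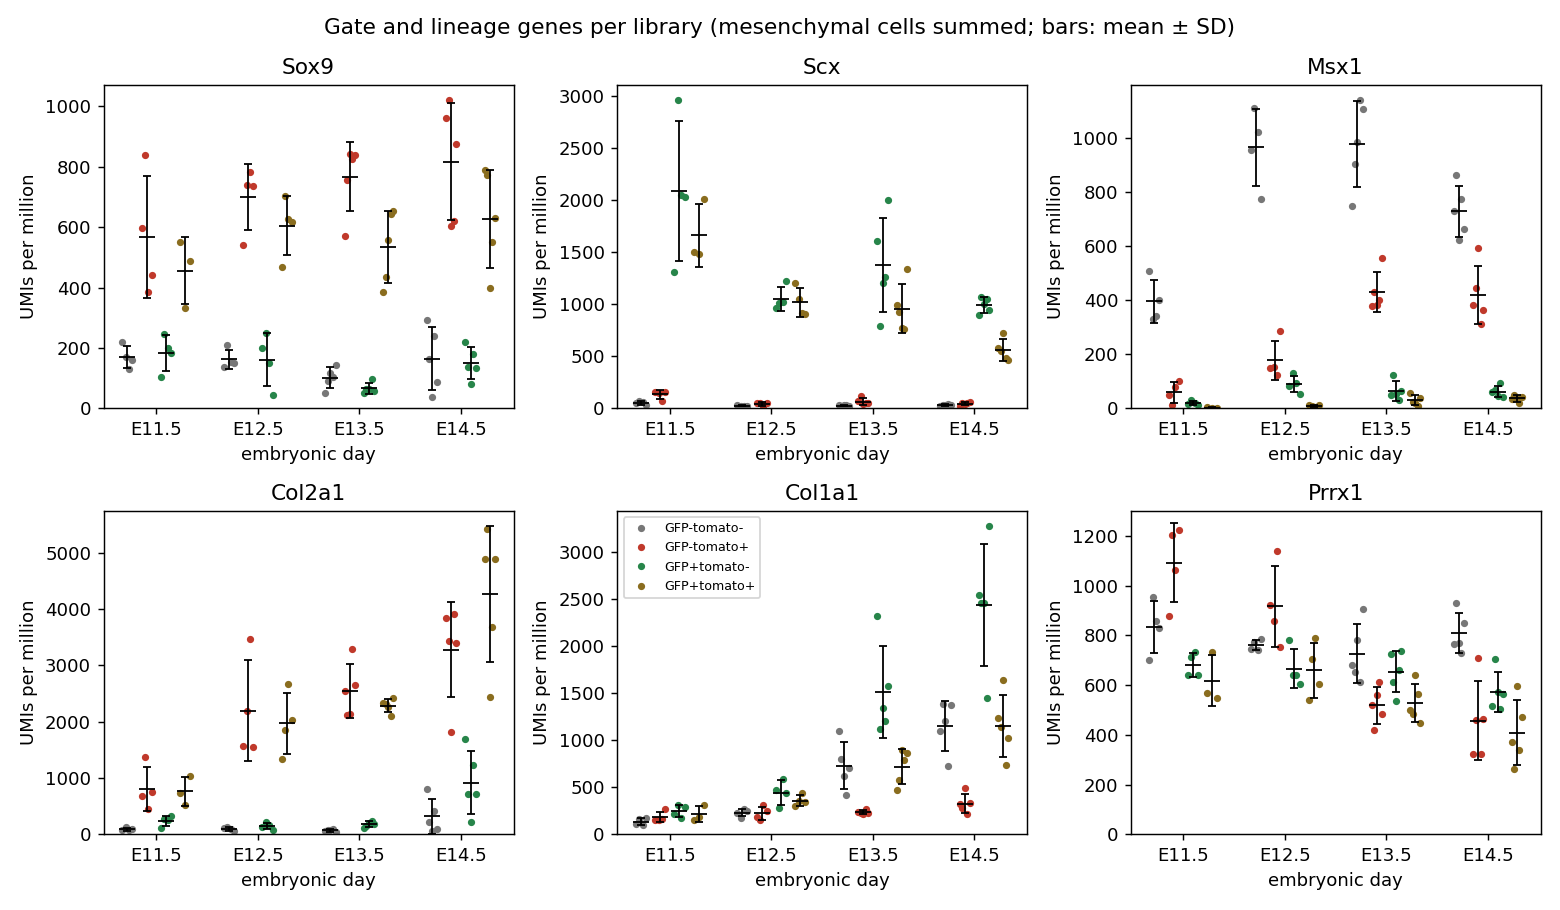
Level of Sox9, Scx, Msx1, Col2a1, Col1a1 and Prrx1 (vertical axes, CPM over mesenchymal cells) by embryonic day (horizontal axes) in the 4 gates, 1 point per library, with bars for the mean and SD of each group. Sox9 and Col2a1 lie highest in the tomato+ gates, Scx in the GFP+ gates, and Msx1 in the double-negative gate, with 978 ± 159.8 CPM at E13.5 against 430.4 ± 74.2 CPM in tomato-only cells.

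Tomato-only cells were compared with double-negative cells to find what cells of the recent Sox9 lineage express when the tendon reporter is off. Sox9 was higher by 2.29 ± 0.17 on the log2 scale (± SE, mean of the 4 stages, 18 libraries against 18) and Scx by 1.01 ± 0.14, while Msx1 was lower, at -1.76 ± 0.16. The cartilage program rose with Sox9. In the chondrocyte list, 21 of the 25 members tested rose (21 adjusted over the list alone, camera adjusted p = 2.6e-76). Its members included Col2a1, the main cartilage collagen (4.10 ± 0.25), the type IX collagen gene Col9a3 (3.63 ± 0.23), and the growth factor receptor Fgfr3 (2.49 ± 0.17). The ubiquitin ligase gene Wwp2 (3.29 ± 0.16), Col11a2 (4.12 ± 0.42), and Cnmd, which codes for chondromodulin (5.22 ± 0.39), belong to it too. The secreted cartilage protein gene Mia (4.62 ± 0.38) and Rflna (3.87 ± 0.30) also rose. Every gene named so far had an adjusted p of at most 1.4e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Acan (aggrecan), Matn1, Matn4 and Cytl1 were among the largest rises too, but had 0 UMIs in double-negative cells at E11.5, so levels are given in place of a fold. At E14.5 Acan stood at 104 ± 25.0 against 13.5 ± 17.1 CPM, and Matn1 at 125 ± 48.4 against 9.76 ± 10.6 CPM (n = 5).

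Other skeletal genes moved with cartilage in tomato-only cells. Of the growth plate genes, 4 of 10 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 6.5e-10). Among them were Runx2, a transcription factor of osteoblasts and hypertrophic chondrocytes (1.95 ± 0.25), and Mef2c (1.61 ± 0.17), while Dlx5 fell (-1.22 ± 0.31). Of the joint interzone genes, 8 of 12 rose (8 and 1 adjusted over the list alone, camera adjusted p = 3.5e-09). They were led by Sfrp2 (1.54 ± 0.11), Sulf1 (1.55 ± 0.15), Erg (2.03 ± 0.20) and Gdf5, a signal of forming joints (1.56 ± 0.20). In the BMP pathway list the antagonist Nog rose (3.43 ± 0.21) and the ligand gene Bmp4 fell (-1.47 ± 0.21). The hedgehog receptor and target Ptch1 rose (1.47 ± 0.17). These genes had adjusted p-values of at most 0.00313 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

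Progenitor genes ran the other way in the same comparison. In the limb progenitor list, which holds homeobox and bHLH genes of undifferentiated limb mesenchyme, 10 of the 15 members tested fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 2.4e-14). Prrx2 (-1.51 ± 0.10), Twist1 (-1.58 ± 0.12) and Msx2 (-1.55 ± 0.16) fell, and Hmga2 rose (0.61 ± 0.13). Of the FGF response genes, 8 of 10 fell (8 adjusted over the list alone, camera adjusted p = 2.5e-10), such as Dusp6, a phosphatase induced by FGF signalling (-1.21 ± 0.15), and Spry1 (-1.84 ± 0.23). Of the autopod genes, 5 of 12 fell (8 and 1 adjusted over the list alone, camera adjusted p = 6.3e-05), including Hoxd13 (-0.72 ± 0.14) and Hoxa13 (-0.56 ± 0.16). Of the cell cycle genes, 12 of 18 fell (16 adjusted over the list alone, camera adjusted p = 8.2e-12), including Pcna (-0.64 ± 0.08) and Rrm2 (-0.82 ± 0.10). Nkd2, an inhibitor of Wnt signalling (-2.78 ± 0.24), Apcdd1 (-2.47 ± 0.30) and Crabp1, a retinoic acid binding protein gene (-2.26 ± 0.22), were also lower. The adjusted p of each of these genes was at most 0.00991 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

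Markers of other cell types moved with the gate as well. Of the erythroid genes, 7 of 7 fell (7 adjusted over the list alone, camera adjusted p = 9.2e-16), although erythroid-like cells had been removed. Hbb-y was one of them (-3.97 ± 0.80), and the near-identical copies Hba-a1 with Hba-a2 and Hbb-bs with Hbb-bt may share reads. Sox10 (3.71 ± 0.51), a transcription factor gene of the neural crest, was higher in tomato-only cells, and Acta2, a smooth muscle actin gene, was lower (-2.50 ± 0.53). Both tested muscle genes, Actc1 and Tnnt1, were lower. The lists that did not pass camera were hedgehog response (1 of 6 rose, 2 fell), osteoblast and perichondrium (3 of 9 rose, 3 fell), tendon (4 of 21 rose, 6 fell) and connective tissue fibroblast (2 of 15 rose, 3 fell). The proximal limb (2 of 14 rose, 3 fell), BMP pathway (3 of 14 rose, 5 fell) and dissociation stress lists (1 of 11 rose, 1 fell) did not pass either. Their camera adjusted p-values ran from 0.151 to 0.816. Further lists without a call were ectoderm (1 of 4 rose, 1 fell), neural crest and Schwann (2 of 3 rose, 1 fell), and pericyte and smooth muscle (1 of 3 rose, 2 fell). The endothelial and macrophage lists, with 3 genes tested in each, did not pass. For these the camera adjusted p ran from 0.140 to 0.816. Adjusted over the list alone, 3 macrophage genes fell.

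Over the 11366 genes tested, 1584 differed between tomato-only and double-negative cells at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 838 higher and 746 lower. All 8 gene lists that passed camera also passed with an estimated correlation. Stage by stage the count of genes was 300 at E11.5, 602 at E12.5, 603 at E13.5 and 618 at E14.5. Msx1 differed by -2.77 ± 0.35 at E11.5, -2.35 ± 0.33 at E12.5 and -1.14 ± 0.28 at E13.5. At E14.5 the difference was -0.77 ± 0.28, which missed the threshold (adjusted p = 0.112 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without the mesenchymal selection, with all cells summed, the count was 2383.

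GFP-only cells were compared with double-negative cells to describe Scx reporter cells without the tomato label. How completely tomato labels Sox9-expressing cells was not tested. Without thinning, 20.4% of E11.5 GFP-only and 24.2% of double-negative cells held a Sox9 UMI. Scx was higher by 5.29 ± 0.14 (log2 ± SE, 18 libraries against 18) and Msx1 was lower, at -3.79 ± 0.18. Sox9 did not pass (-0.15 ± 0.17). Of the tendon genes, 15 of 21 rose (15 adjusted over the list alone, camera adjusted p = 1.1e-33). Fmod (2.90 ± 0.37) and Lum (2.55 ± 0.26), which code for collagen-binding proteoglycans, and Col1a1 (0.99 ± 0.14) were among them. Keratocan (Kera) had 0 UMIs in double-negative cells at E11.5 and E12.5 and stood at 108 ± 56.5 against 2.44 ± 2.29 CPM at E13.5. Of the connective tissue fibroblast genes, 13 of 15 rose (14 adjusted over the list alone, camera adjusted p = 3.2e-27). They included Osr2 (2.73 ± 0.27), Dlk1 (2.55 ± 0.22) and the growth factor receptor gene Pdgfra (1.17 ± 0.12). The transcription factor genes Ebf2 (3.73 ± 0.29) and Six2 (3.00 ± 0.17), the growth factor gene Fgf18 (2.92 ± 0.22) and Angptl1 (3.00 ± 0.33) also rose. All of these but Sox9 had adjusted p-values of at most 1.0e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

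Along the limb axis the GFP-only cells differed from the double-negative cells in both directions. Proximal limb genes were higher (7 of 14 higher, 8 adjusted over the list alone, camera adjusted p = 1.6e-07), such as Shox2 (1.39 ± 0.16), Emx2 (1.74 ± 0.27) and Meis2 (1.46 ± 0.24). Autopod genes were lower (6 of 12 lower and 1 higher, 7 and 1 adjusted over the list alone, camera adjusted p = 4.7e-11), such as Hoxa13 (-1.21 ± 0.17) and Tfap2b (-2.63 ± 0.23), while Epha7 rose (1.16 ± 0.17). Limb progenitor genes fell (11 of 15 lower and 2 higher, 11 and 2 adjusted over the list alone, camera adjusted p = 3.2e-27), with Msx2 (-3.20 ± 0.19), Lhx9 (-2.60 ± 0.11) and Lhx2 (-2.36 ± 0.16). FGF response genes fell (camera adjusted p = 2.5e-07), although Spry2 rose (1.39 ± 0.14). In the BMP pathway list (camera adjusted p = 9.1e-07) the BMP targets Id1 (-1.04 ± 0.10) and Id3 (-1.17 ± 0.08) and the pseudoreceptor gene Bambi (-2.35 ± 0.14) fell. The antagonist Grem1 rose (1.59 ± 0.32). Joint interzone genes rose (camera adjusted p = 4.4e-05), and cell cycle (camera adjusted p = 7.5e-07) and erythroid genes (camera adjusted p = 5.1e-22) fell. For these genes the adjusted p was at most 2.4e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

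In all, 936 genes differed between GFP-only and double-negative cells (587 higher, 349 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 13 lists past the threshold in camera, 10 passed with an estimated correlation. The chondrocyte list (camera adjusted p = 0.00873, 0.482 with an estimated correlation) was 1 of the others, with Col2a1 higher by 1.25 ± 0.23 and Fgfr3 lower, at -1.13 ± 0.22. Growth plate (camera adjusted p = 0.00107, 0.0531 with an estimated correlation) and ectoderm (camera adjusted p = 0.0198, 0.0717 with an estimated correlation) were the rest. Among markers of other cell types 1 of 2 muscle genes was higher and 1 of 3 neural crest and Schwann genes lower.

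Double-positive cells were set against each single-colour gate to see which program cells carrying both reporters express. Against tomato-only cells, Scx was higher by 3.89 ± 0.13 and Msx1 was lower, at -3.86 ± 0.22 (log2 ± SE, 17 libraries against 18). Of the tendon genes, 14 of 21 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 2.6e-31). They included Mkx, a tendon transcription factor (1.99 ± 0.26), Col3a1 (1.17 ± 0.14) and Col1a1 (1.10 ± 0.14). Connective tissue fibroblast genes (camera adjusted p = 3.0e-13) such as Dlk1 (1.74 ± 0.21) and Ogn (1.84 ± 0.27) were higher. So were proximal limb genes (camera adjusted p = 4.5e-08) such as Shox2 (1.56 ± 0.19) and Meis2 (1.74 ± 0.28). Limb progenitor (camera adjusted p = 1.0e-22), autopod (camera adjusted p = 3.6e-19) and growth plate genes (camera adjusted p = 5.3e-08) were lower. Among them were Msx2 (-2.96 ± 0.24), Lhx2 (-2.14 ± 0.17), Hoxa13 (-2.14 ± 0.20), Hoxd13 (-1.64 ± 0.16) and Mef2c (-1.27 ± 0.17). The retinoic acid synthesis gene Aldh1a2 was lower too (-2.75 ± 0.31). Sox9 did not pass (-0.34 ± 0.17), nor did the chondrocyte list (camera adjusted p = 0.522). Sox9 had an adjusted p of 0.356 and the other genes named here of at most 8.4e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

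Against GFP-only cells, double-positive cells were higher in Sox9 by 2.10 ± 0.18. Of the chondrocyte genes, 19 of 25 rose (22 adjusted over the list alone, camera adjusted p = 8.5e-88). Cnmd (4.26 ± 0.34), Col9a3 (2.89 ± 0.22), Col2a1 (2.86 ± 0.23), Fgfr3 (2.64 ± 0.20) and Wwp2 (2.62 ± 0.16) were in this list. Growth plate (camera adjusted p = 2.0e-09), joint interzone (camera adjusted p = 2.6e-07) and BMP pathway genes (camera adjusted p = 0.00191) were higher too. Runx2 (1.61 ± 0.26), Gdf5 (2.13 ± 0.20), Nog (2.70 ± 0.27) and Chrdl1 (2.07 ± 0.24) belong to these. Tendon (camera adjusted p = 1.6e-07), connective tissue fibroblast (camera adjusted p = 4.2e-09) and limb progenitor genes (camera adjusted p = 1.6e-07) were lower. So were FGF response (camera adjusted p = 5.2e-04) and autopod genes (camera adjusted p = 6.9e-07). Falls were seen for Dcn (-2.45 ± 0.28), Lum (-1.34 ± 0.22), Twist1 (-1.48 ± 0.13), Il17rd (-1.26 ± 0.18), Hoxd13 (-1.52 ± 0.16) and Msx1 (-1.83 ± 0.23). Markers of other cell types moved too: both muscle genes tested were lower (median -2.81), and of 3 neural crest and Schwann genes 2 were higher and 1 lower. Muscle-like cells, 610 of them in the GFP-only and 2 in the double-positive gate, had been removed before these sums. Scx itself was lower by a small step, at -0.39 ± 0.11, which missed the threshold with all cells summed and without litter 20.2. Each gene given with a fold against GFP-only cells had an adjusted p of at most 0.0177 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

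The double-positive gate differed from the tomato-only gate in 430 genes (250 higher, 180 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. From the GFP-only gate it differed in 999 (504 higher, 495 lower). With the later of 2 read formats alone the counts were 224 and 488, and with all cells summed the second was 1586. At E11.5 alone the double-positive and GFP-only gates differed in 7 genes, against 431 at E14.5. Camera passed 9 lists in the first comparison and 10 in the second, of which 6 and 9 passed with an estimated correlation. In the first the others were joint interzone (camera adjusted p = 0.00887, 0.105 with an estimated correlation), BMP pathway (camera adjusted p = 0.00696, 0.0553 with an estimated correlation) and dissociation stress (camera adjusted p = 0.00887, 0.130 with an estimated correlation). In the second it was dissociation stress (camera adjusted p = 0.00339, 0.0900 with an estimated correlation).

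**Figure D2:**
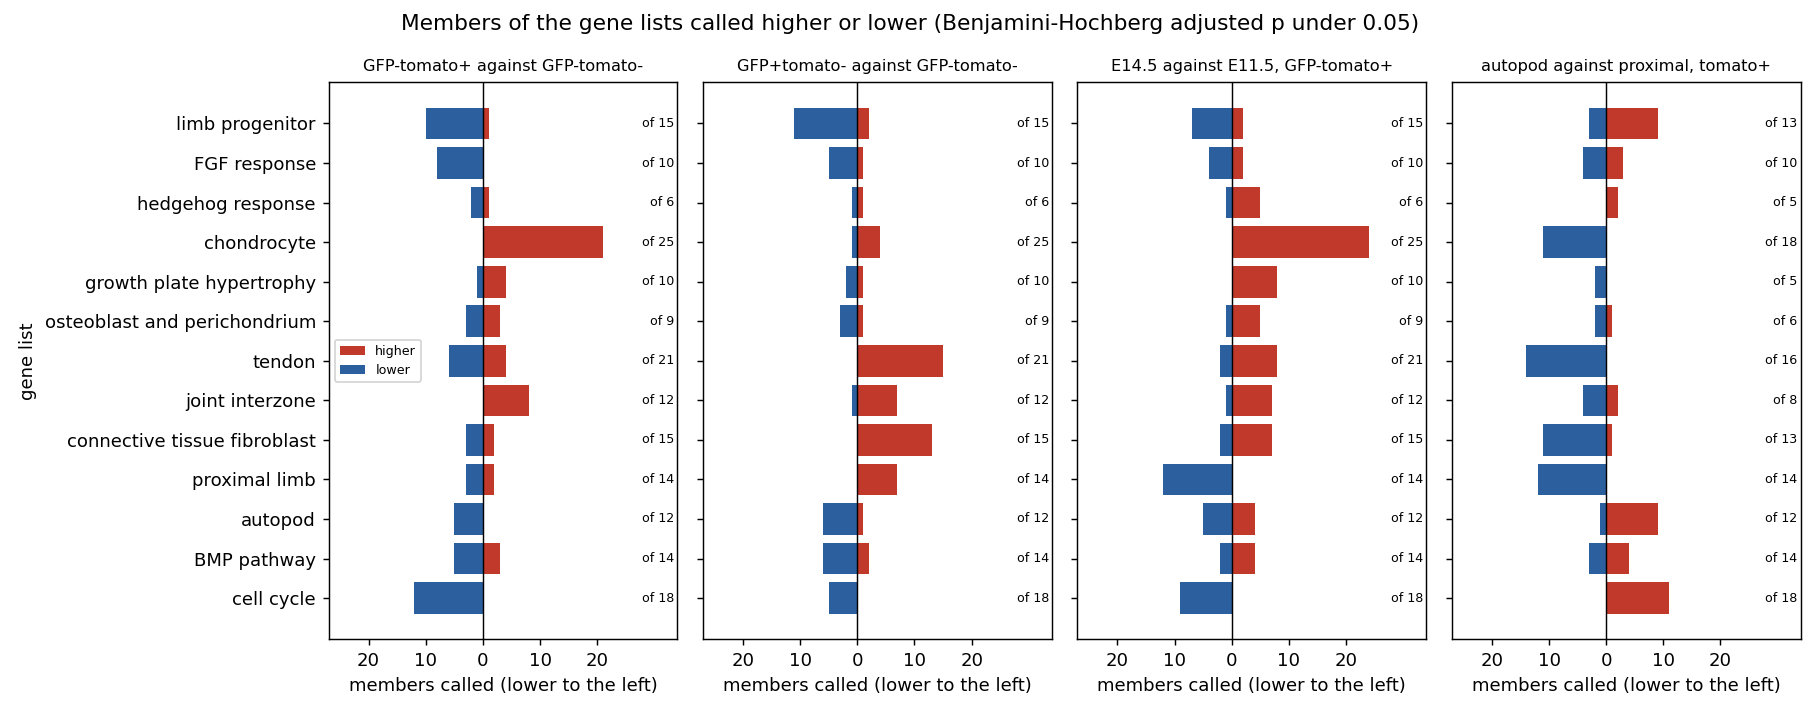
Number of members of 13 gene lists (vertical axis) that were higher (bars to the right) or lower (bars to the left) at an adjusted p under 0.05 in 4 comparisons, 1 panel each. The panels show tomato-only against double-negative, GFP-only against double-negative, E14.5 against E11.5 in tomato-only cells, and autopod against proximal in tomato+ cells. In the first panel the chondrocyte bar reaches 21 of 25 genes to the right and the limb progenitor bar 10 of 15 to the left.

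E14.5 was compared with E11.5 within each gate to follow how the programs change as the skeleton forms. In tomato-only cells (5 libraries against 4) Msx1 rose by 2.96 ± 0.34 (log2 ± SE) and Scx fell, at -1.42 ± 0.26. Sox9 did not pass (0.66 ± 0.33, adjusted p = 0.20 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cartilage genes rose (24 of 25 rose, 25 adjusted over the list alone, camera adjusted p = 2.2e-41). Acan (5.39 ± 0.63), the link protein gene Hapln1 (7.75 ± 0.95) and Papss2, an enzyme gene of sulfate activation (3.72 ± 0.46), were among them. Growth plate genes rose with them (8 of 10 rose, 9 adjusted over the list alone, camera adjusted p = 2.8e-17). Ihh, the hedgehog ligand of prehypertrophic chondrocytes, went from 0 to 190 UMIs and was at least 74.8-fold higher against a floor of 3 counts over the group. Runx3 went from 1 to 207 UMIs. Hedgehog response genes rose (camera adjusted p = 3.6e-07), with Ptch1 (2.12 ± 0.32), Gli1 (2.37 ± 0.46) and Hhip (5.99 ± 0.66), while Grem1 went from 39 to 2 UMIs. Joint interzone (camera adjusted p = 2.8e-09), tendon (camera adjusted p = 2.7e-05), connective tissue fibroblast (camera adjusted p = 4.0e-06) and osteoblast genes (camera adjusted p = 8.1e-04) rose as groups. Gdf5 (3.50 ± 0.38), Bgn (2.52 ± 0.29), Ogn (5.46 ± 0.65) and Mef2c (2.79 ± 0.32) are members.

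Genes of early and proximal limb fell in tomato-only cells over the same interval. Of the proximal limb genes, 12 of 14 fell (13 adjusted over the list alone, camera adjusted p = 3.5e-20). Shox2 changed by -4.06 ± 0.41, Tbx15 by -2.56 ± 0.27, Tbx18 by -2.77 ± 0.28 and Meis2 by -4.20 ± 0.60. Emx2 went from 170 UMIs to 0, at least 48.0-fold lower against a floor of 3 counts over the group. Limb progenitor (camera adjusted p = 0.00161), FGF response (camera adjusted p = 0.0120) and cell cycle genes (camera adjusted p = 1.2e-05) fell. With E12.5 in place of E11.5 the cell cycle list turned upwards without passing (camera adjusted p = 0.0765). Members that fell were Hmga2 (-2.76 ± 0.28), Prrx1 (-1.14 ± 0.16), Lhx9 (-1.50 ± 0.21), Dusp6 (-2.48 ± 0.30) and Pcna (-0.83 ± 0.16). The secreted Wnt antagonist gene Frzb (-5.54 ± 0.52) and the steroid enzyme gene Hsd11b2 (-5.19 ± 0.53) were among the largest falls. Hoxd13 rose (1.70 ± 0.30) while the autopod list as a whole did not pass (camera adjusted p = 0.896). All folds given here for the tomato-only gate, except that of Sox9, had adjusted p-values of at most 8.9e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

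In double-negative cells the same interval brought connective tissue fibroblast genes up (13 of 15 rose, 14 adjusted over the list alone, camera adjusted p = 3.6e-28). Postn rose by 7.01 ± 0.67, Ogn by 6.77 ± 0.64, Dcn by 6.97 ± 0.75 and Col6a3 by 3.01 ± 0.30. Tendon (camera adjusted p = 1.2e-15), joint interzone (camera adjusted p = 1.7e-10), osteoblast (camera adjusted p = 2.5e-05) and growth plate genes (camera adjusted p = 3.0e-06) rose. Col1a1 (3.15 ± 0.30), Osr1 (4.00 ± 0.37) and Mef2c (3.89 ± 0.39) are members of these lists. Hic1, a transcriptional repressor gene, went from 0 to 171 UMIs and was at least 79.6-fold higher against the floor of 3 counts. FGF response (camera adjusted p = 3.9e-06) and cell cycle genes (camera adjusted p = 4.8e-13) fell, with Dusp6 (-2.82 ± 0.27) and Rrm2 (-1.78 ± 0.21). Msx1 rose by 0.96 ± 0.30, a call lost without the filter on low counts (0.90, adjusted p = 0.0692), with all cells summed (0.63, adjusted p = 0.115) and without litter 29 (0.90, adjusted p = 0.0636) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among globins Hbb-y, an embryonic form, fell (-5.72 ± 1.16) and Hbb-bs, an adult form, rose (7.29 ± 0.91). Of the 2 muscle genes tested 1 rose. The adjusted p of each of these folds was at most 0.0198 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

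In GFP-only cells tendon genes rose most clearly as a list (18 of 21 rose and 1 fell, 19 and 1 adjusted over the list alone, camera adjusted p = 1.3e-29). Among single genes Bgn (4.00 ± 0.30), Col1a1 (3.39 ± 0.30), Htra1 (6.21 ± 0.61), Col6a2 (3.18 ± 0.33) and Cnmd (4.48 ± 0.66) rose. Hmga2 (-2.77 ± 0.27) and Hmgb2 (-1.40 ± 0.17) fell. Msx1 was higher by 1.59 ± 0.40 and Scx changed by -0.98 ± 0.22. In the later read format alone the Msx1 rise missed the threshold (1.20, adjusted p = 0.109 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). These folds had adjusted p-values of at most 0.00263 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Chondrocyte (camera adjusted p = 3.7e-13), connective tissue fibroblast (camera adjusted p = 3.2e-09), joint interzone (camera adjusted p = 1.1e-07) and osteoblast genes (camera adjusted p = 2.0e-04) also rose as lists. So did hedgehog response (camera adjusted p = 0.0363) and growth plate genes (camera adjusted p = 0.00300, 0.0874 with an estimated correlation). With E12.5 in place of E11.5 the hedgehog list turned downwards without passing (camera adjusted p = 0.813). Of the 2 muscle genes tested 1 rose (2 adjusted over the list alone, median 3.93), 2 of 3 pericyte and smooth muscle genes rose, and 1 of 3 macrophage genes fell (3 adjusted over the list alone). Cell cycle (camera adjusted p = 2.6e-18), proximal limb (camera adjusted p = 4.6e-08) and limb progenitor genes (camera adjusted p = 0.0121, 0.0982 with an estimated correlation) fell. In double-negative cells the chondrocyte (camera adjusted p = 9.0e-08, 0.157 with an estimated correlation) and autopod lists (camera adjusted p = 0.00272, 0.103 with an estimated correlation) passed only with the preset correlation. Thus 7 of 9 lists passed both ways in double-negative, 8 of 10 in GFP-only and 11 of 11 in tomato-only cells.

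From E11.5 to E14.5, 1810 genes changed in double-negative cells (1008 higher, 802 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 1350 in tomato-only (709 higher, 641 lower) and 1813 in GFP-only cells (987 higher, 826 lower). With only the groups compared in the fit the counts were 1226, 899 and 1086. With the later read format alone these counts were 1062, 853 and 1045. With E12.5 in place of E11.5 they were 978, 342 and 1090. Cells were released with trypsin at E11.5 and with collagenase at E12.5 and E14.5, so stage and enzyme changed together only in the comparison with E11.5. Between E12.5 and E14.5 Msx1 rose in tomato-only cells (1.24). It stood at -0.34 in double-negative and -0.53 in GFP-only cells, the opposite sign to the change from E11.5. Scx showed next to no change from E12.5 to E14.5 in tomato-only (-0.0076) and GFP-only cells (-0.033). Of 12 sequencing batches only 1 held both E11.5 and E14.5 libraries, those of litters 27 and 30, too few for a test within it. There Msx1 stood at 12.4 CPM at E11.5 and 364 CPM at E14.5 in tomato-only cells. It stood at 331.5 and 664 CPM in double-negative cells, and 31.4 and 41.2 CPM in GFP-only cells.

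The stage changes of tomato-only and double-negative cells were then tested against each other. Msx1 rose by 2.00 ± 0.44 more in tomato-only cells (log2 difference ± SE, adjusted p = 0.00332 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while Sox9 (0.64 ± 0.47) and Scx (-0.73 ± 0.40) did not pass. With only the groups compared in the fit the Msx1 difference kept its size but missed the threshold (2.01, adjusted p = 0.0595 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The FGF-responsive transcription factor gene Etv5 (2.17 ± 0.44), Lhx2 (1.84 ± 0.41) and Hoxd13 (1.67 ± 0.40) also changed more positively there. So did the proprotein convertase gene Pcsk6 (2.71 ± 0.61) and Col9a1 (1.77 ± 0.41). The chemokine genes Cxcl12 (-4.85 ± 0.53) and Cxcl14 (-4.74 ± 0.58), Tbx18 (-3.90 ± 0.38), Osr2 (-4.63 ± 0.80) and Lum (-4.44 ± 0.93) changed more negatively. Ebf2 (-5.04 ± 0.96), Col1a1 (-2.19 ± 0.39), Col1a2 (-1.98 ± 0.33), Sfrp2 (-2.02 ± 0.32) and Prrx1 (-1.18 ± 0.23) did as well. Proximal limb (9 of 14 more negative, 9 adjusted over the list alone, camera adjusted p = 1.6e-13), connective tissue fibroblast (camera adjusted p = 6.8e-19) and tendon differences (camera adjusted p = 2.8e-07) were negative as groups. Hedgehog response (camera adjusted p = 2.9e-05), chondrocyte (camera adjusted p = 8.1e-19) and growth plate differences (camera adjusted p = 3.2e-04) were positive.

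Each gene difference named for this test, Sox9 and Scx aside, had an adjusted p of at most 0.010 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In total 233 genes differed in their stage change (49 more positive and 184 more negative in tomato-only cells) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 382 with the litter as a block and 98 with the later read format alone. Of 10 lists past the threshold in camera 6 passed with an estimated correlation. The others were FGF response (camera adjusted p = 0.0204, 0.0656 with an estimated correlation), autopod (camera adjusted p = 8.3e-04, 0.0656 with an estimated correlation), cell cycle (camera adjusted p = 1.1e-04, 0.0656 with an estimated correlation) and dissociation stress (camera adjusted p = 0.0328, 0.245 with an estimated correlation). For FGF response the median (-0.00101) and the mean (0.36) had different signs.

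Msx1 was also read per cell, after each cell was thinned to 1000 UMIs. The share of cells with a UMI depends on both the number of cells with Msx1 and its level, and does not separate them. In double-negative cells the share of mesenchymal cells with an Msx1 UMI was 24.5% ± 4.89 (SD, n = 4) at E11.5 and 52.2% ± 5.24 (n = 4) at E12.5. It was 46.3% ± 5.91 (n = 5) at E13.5 and 37.9% ± 6.17 (n = 5) at E14.5. In tomato-only cells it was 3.82% ± 1.83, 9.86% ± 4.21, 25.7% ± 6.23 and 22.8% ± 3.50 at the same stages. In tomato-only cells the share was 19.0 percentage points higher at E14.5 than at E11.5 (exact two-sided permutation test, p = 0.00794, the smallest p that 126 splits allow). In double-negative cells it was 13.5 points higher (exact two-sided permutation test, p = 0.0238). Without thinning the shares were 7.94% and 32.3% in tomato-only and 38.4% and 46.9% in double-negative cells. The unthinned double-negative rise of 8.46 points missed the threshold (p = 0.286, exact two-sided permutation test). So did that of 8.55 points after thinning to 2000 UMIs (p = 0.143, exact two-sided permutation test). Leaving out 1 of the 9 libraries of the double-negative comparison gave rises of 11.6 to 15.7 points. The test then missed the threshold in 7 of the 9 cases, all but those without litter 11 or litter 24.

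Averaged over stages, the share was lower in tomato-only than in double-negative cells (-24.7 points, 18 libraries against 18). The permutation test within stages, two-sided, gave p = 1e-05, the smallest that 100000 resamples give. As background, 3.87% of erythroid-like cells held an Msx1 UMI after thinning (7 of 181 cells, exact 95% interval 1.57 to 7.81%, 8.74% without thinning). Their median was 1961.5 UMIs per cell, against 2004 in mesenchymal cells. The E11.5 tomato-only share and the GFP-only and double-positive shares at E11.5 (1.64% ± 0.503 and 0.152% ± 0.262) lay at or below this level. Muscle-like cells gave a lower level (20 of 1173 cells, 1.71%, exact 95% interval 1.04 to 2.62%, median 3096 UMIs). Macrophage-like (3.32%), endothelial-like (5.04%) and Schwann-like cells (0.794%, 1 of 126, exact 95% interval 0.0201 to 4.34%) varied as widely. Of the erythroid-like cells in the 4 gates 126 were double-negative and 2 tomato-only, so their level may not hold for tomato-only plates. At E11.5 the double-positive share lay below all these levels, and the GFP-only share below all but the Schwann-like one. Both are read as background. The tomato-only share lay within the range of the levels, so whether it exceeds background is open. Thinning left out 194 and 134 shallow double-negative cells at E11.5 and E14.5, and 88 and 228 tomato-only cells.

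Within tomato-only cells, Msx1 and Col2a1 were found in the same cell less often than independence gives. The mean log odds ratio over 18 libraries was -1.05 ± 0.802 (SD), below 0 in 17 of 18. A two-sided sign-flip permutation test gave p = 4e-05 (Benjamini-Hochberg adjusted p = 0.00036 over 9 such tests). The other 8 tests, of Msx1 with Col2a1 or Scx and of Sox9 with Scx in the tomato-only and GFP+ gates, missed the threshold after adjustment. The nearest was Msx1 with Scx in GFP-only cells (-0.535 ± 0.833, below 0 in 16 of 18 libraries, permutation adjusted p = 0.0611). In libraries with few Msx1 cells the 0.5 added to each cell of the table moves the log odds ratio off 0 by itself. Group means of the Msx1 share were at most 5.52% in GFP-only and 2.83% in double-positive cells. Their Msx1 odds ratios are therefore not read for direction. The E11.5 tomato-only libraries (3.82%) are open to the same shift.

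**Figure D3:**
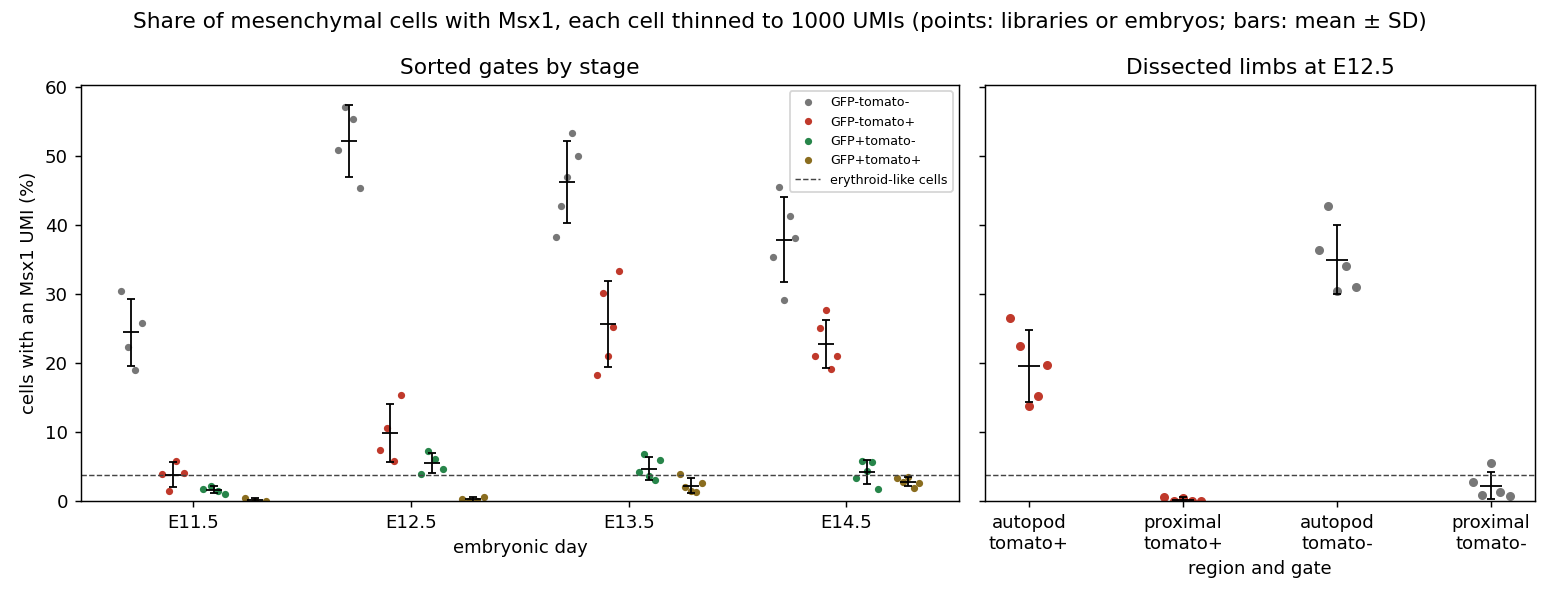
Share of mesenchymal cells with an Msx1 UMI (vertical axes, percent, cells thinned to 1000 UMIs) by embryonic day in the 4 gates (left) and by region and gate in dissected E12.5 limbs (right), 1 point per library or embryo with bars for the mean and SD. The dashed line marks the 3.87% of erythroid-like cells with an Msx1 UMI, and the tomato-only share lies at 3.82% ± 1.83 at E11.5 and 25.7% ± 6.23 at E13.5.

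At E10.5 cells were sorted on Sox9-GFP to describe the earliest Sox9-expressing limb cells. Sox9 was higher by 4.21 ± 0.49 in the positive cells (log2 ± SE, 3 libraries against 3). Col2a1 (4.11 ± 0.38), Scx (2.27 ± 0.45), Foxc1 (5.97 ± 0.89), Emx2 (3.66 ± 0.40), Cxcl12 (2.99 ± 0.24) and Irx3 (2.59 ± 0.32) were higher with it. Msx1 was lower, at -3.96 ± 0.51, with Msx2 (-3.63 ± 0.41) and the T-box gene Tbx2 (-3.50 ± 0.42). Grem1 (-2.65 ± 0.28), Bmp4 (-2.46 ± 0.31) and Mycn (-1.60 ± 0.25) were lower too. Pax3 (110 UMIs) and Lbx1 (81 UMIs), transcription factor genes of migrating muscle precursors, had UMIs in Sox9-GFP-negative cells and 0 in positive cells. They were at least 26.8-fold and 19.7-fold lower against the floor of 3 counts. With 3 libraries a side the genes named at E10.5 had adjusted p-values of at most 0.0431 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

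At E10.5 128 of 9881 genes passed (76 higher, 52 lower), against 517 with the replicate number as a block, 358 without a filter on low counts and 15 with the plates of replicate 22 summed into 1 sample per gate, at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With these plates summed, 26 of the 38 genes that the naming rule picks lost their call, among them Sox9 (4.15, adjusted p = 0.0695), Msx1 (-3.82, adjusted p = 0.0822) and Scx (2.46, adjusted p = 0.149) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Foxc1, Bmp4, Mycn, Pax3 and Lbx1 lost theirs too, and Col2a1, Emx2, Cxcl12, Irx3, Msx2, Tbx2 and Grem1 kept it. Msx1 also missed the threshold with all cells summed, and Scx without the mitochondrial limit and in 4 of 6 fits without 1 library. The count moved with single libraries. It was 81 or 34 without either negative library of replicate 22, and 47 or 61 without either positive library of replicate 22. It was 267 without the positive and 104 without the negative library of replicate 25. Camera passed 10 lists with the preset correlation, and with an estimated one their adjusted p-values were 0.0510 or more. Proximal limb (8 of 14 higher and 1 lower, 10 and 3 adjusted over the list alone, camera adjusted p = 2.9e-07, adjusted p = 0.0510 with an estimated correlation) and chondrocyte genes (camera adjusted p = 9.3e-08, 0.0689 with an estimated correlation) were higher. Limb progenitor (camera adjusted p = 3.6e-07, 0.0689 with an estimated correlation), FGF response (camera adjusted p = 6.3e-11, 0.0510 with an estimated correlation) and autopod genes (camera adjusted p = 4.4e-05, 0.0689 with an estimated correlation) were lower. The other lists were hedgehog response (camera adjusted p = 2.6e-06, 0.0689 with an estimated correlation) and BMP pathway (camera adjusted p = 0.00159, 0.283 with an estimated correlation), which were lower. Tendon (camera adjusted p = 0.00671, 0.383 with an estimated correlation), joint interzone (camera adjusted p = 0.00174, 0.123 with an estimated correlation) and connective tissue fibroblast (camera adjusted p = 2.4e-04, 0.144 with an estimated correlation) were higher.

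The E12.5 autopod was compared with the proximal limb to place these programs along the limb. In tomato+ cells (5 embryos, with embryo as a block) Msx1 was higher in the autopod by 6.60 ± 0.49 (log2 ± SE) and Scx was lower, at -1.91 ± 0.27. Sox9 did not pass (0.24 ± 0.15, adjusted p = 0.384 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the autopod genes, 9 of 12 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 3.2e-15). Hoxd13 (5.60 ± 0.24), Hoxd12 (3.79 ± 0.18) and Hoxa13 (3.38 ± 0.25) were among them. Evx2 and Tfap2b had 301 and 231 UMIs against 0, at least 104-fold and 79.7-fold higher against the floor of 3 counts. Limb progenitor (9 of 13 higher and 3 lower, 9 and 4 adjusted over the list alone, camera adjusted p = 9.7e-07) and cell cycle genes (camera adjusted p = 1.1e-09) were higher there too. Msx2 (3.12 ± 0.26), Lhx2 (2.57 ± 0.20), Aldh1a2 (3.86 ± 0.39), the guidance gene Slit2 (2.61 ± 0.34) and Top2a (1.07 ± 0.12) were higher. The hedgehog response list passed upwards (camera adjusted p = 0.00392) with a median of -0.29 and a mean of 1.59, and the members that moved were Hoxd12 and Hoxd13.

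Proximal tomato+ cells were higher in proximal limb genes (12 of 14 lower, 12 and 1 adjusted over the list alone, camera adjusted p = 1.6e-19 in the autopod). Shox2 (-4.97 ± 0.20) and Emx2 (-4.48 ± 0.41) were lower in the autopod, and Meis2 had 343 proximal UMIs against 1. Tendon (camera adjusted p = 3.9e-23), connective tissue fibroblast (camera adjusted p = 9.2e-19) and chondrocyte genes (11 of 18 lower, 11 and 1 adjusted over the list alone, camera adjusted p = 1.5e-10) were lower in the autopod. Growth plate (camera adjusted p = 0.00392) and osteoblast genes (camera adjusted p = 0.0298, 0.0515 with an estimated correlation) were lower as well. Col3a1 (-3.21 ± 0.14), Cxcl12 (-3.42 ± 0.21), Dlk1 (-5.42 ± 0.22), Col11a1 (-2.05 ± 0.16) and Cnmd (-5.15 ± 0.45) belong to these lists. Runx2 (-3.96 ± 0.40), Col1a1 (-2.60 ± 0.28) and the insulin-like growth factor binding protein gene Igfbp5 (-5.58 ± 0.18) fell too, and Igfbp3 had 426 proximal UMIs against 0. Folds given for tomato+ cells, except that of Sox9, had adjusted p-values of at most 2.9e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An Msx1 UMI was found in 19.6% ± 5.24 of autopod and 0.229% ± 0.316 of proximal tomato+ cells after thinning (SD, n = 5 embryos, 30.7% and 0.622% without thinning). The difference was 19.4 points, in the same direction in all 5 embryos (exact two-sided sign-flip permutation test, p = 0.0625, the smallest that 5 embryos allow). The proximal share lay below every background level given above.

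In tomato- cells Msx1 (4.38 ± 0.37) and Sox9 (1.39 ± 0.24) were higher in the autopod and Scx was lower (-2.12 ± 0.27). Hoxd13 (4.07 ± 0.22), Lhx9 (2.88 ± 0.15) and Bambi (2.47 ± 0.20) were higher. Shox2 (-4.61 ± 0.17), Dlk1 (-6.83 ± 0.23), Lum (-5.36 ± 0.30) and Hic1 (-5.46 ± 0.33) were lower. All of these folds had an adjusted p of at most 1.1e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Autopod (camera adjusted p = 9.2e-10), limb progenitor (camera adjusted p = 6.0e-06) and cell cycle genes (camera adjusted p = 1.3e-11) were higher. Connective tissue fibroblast (camera adjusted p = 3.2e-21), proximal limb (camera adjusted p = 1.5e-16) and tendon genes (camera adjusted p = 4.2e-14) were lower. The hedgehog response (camera adjusted p = 0.0230, 0.112 with an estimated correlation) and erythroid lists (camera adjusted p = 4.4e-06, 0.0758 with an estimated correlation) passed with the preset correlation alone. Muscle-like cells made up 273 of 1436 proximal tomato- cells and 2 of 1478 autopod tomato- cells before they were removed. Both muscle genes tested were lower in the autopod, Actc1 at 1 against 58 UMIs.

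Between regions 987 of 9494 genes differed in tomato+ (391 higher, 596 lower in the autopod) and 1475 in tomato- cells (673 higher, 802 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The regional difference depended on the gate for 148 genes. It was more negative in tomato+ cells for Sox9 (-1.15 ± 0.29), Col9a1 (-1.56 ± 0.26), Sox5 (-2.10 ± 0.42) and Runx2 (-2.89 ± 0.65). It was more positive for Slit2 (3.73 ± 0.48), Aldh1a2 (3.53 ± 0.67) and Rdh10, another retinoic acid synthesis gene (2.52 ± 0.43). Tgfb2 (2.44 ± 0.38) and Tcf7l2 (2.35 ± 0.20) were more positive too, and these genes had an adjusted p of at most 0.0365 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Chondrocyte differences were negative (5 of 18 more negative, 7 adjusted over the list alone, camera adjusted p = 2.6e-17). Growth plate (camera adjusted p = 1.9e-04), osteoblast (camera adjusted p = 0.0119), FGF response (camera adjusted p = 0.00283) and cell cycle differences (camera adjusted p = 0.0179, 0.260 with an estimated correlation) were negative as well. Connective tissue fibroblast (camera adjusted p = 3.2e-04), hedgehog response (camera adjusted p = 0.0353, 0.128 with an estimated correlation) and erythroid differences (camera adjusted p = 2.1e-09) were positive. The count of genes was 137 without Embryo1 and 85 without Embryo2 of litter 1, and 98, 87 and 92 without Embryo1, Embryo2 and Embryo3 of litter 2. The fit without the embryo block gave 92. The Sox9 difference missed the threshold in 3 of 5 fits without 1 embryo (-1.02 to -1.26), without the embryo block (-1.17) and with left limbs alone (-1.07).

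Across both regions of the dissected limbs, tomato+ cells were higher than tomato- cells in Sox9 by 3.18 ± 0.14. Col9a3 (5.51 ± 0.20), Sox6 (4.71 ± 0.23), Hapln1 (4.71 ± 0.49), Foxc1 (4.68 ± 0.16) and Nog (4.31 ± 0.30) were higher. So were Col2a1 (4.18 ± 0.24), Gdf5 (2.80 ± 0.32) and Mef2c (2.22 ± 0.25). Msx1 (-1.90 ± 0.38), Twist1 (-1.18 ± 0.08), Nkd2 (-1.76 ± 0.15), Shox2 (-1.03 ± 0.15) and Hbb-y (-7.33 ± 0.41) were lower. With equal embryo names taken as 1 embryo Msx1 missed the threshold (-1.81). The adjusted p was then 0.0624, against at most 0.00604 for these genes in the main fit, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scx did not pass (0.07 ± 0.19). Chondrocyte (18 of 18 higher, 18 adjusted over the list alone, camera adjusted p = 1.4e-48), joint interzone (camera adjusted p = 1.6e-08) and growth plate genes (camera adjusted p = 0.00153) were higher. Limb progenitor (camera adjusted p = 7.8e-08), FGF response (camera adjusted p = 7.4e-05), cell cycle (camera adjusted p = 3.1e-07) and erythroid genes (camera adjusted p = 1.7e-25) were lower. All 7 lists also passed with an estimated correlation. In total 804 genes passed (463 higher, 341 lower) at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1451 with all cells summed. Without the mitochondrial limit the count was 1366, and that limit removed a median of 37.7% of wells in the 12 tomato+ and 21.2% in the 10 tomato- libraries.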

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

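The tests of neutrophils sorted alone, of the digestion enzyme and of distal cells, and all counts over other splits of the samples, were chosen after the results they concern had been seen. The change from E11.5 to E14.5 differed between tomato-only and double-negative cells in 233 genes, Msx1 among them (2.00), by a test of the difference itself. With only the groups compared in the fit Msx1 missed the threshold (2.01), so this call depends on the fit. The change from proximal limb to autopod differed between tomato+ and tomato- cells in 148 genes, Sox9 among them (-1.15), also by a direct test, but Sox9 missed the threshold in 3 of 5 fits without 1 embryo. For the comparisons of gated cells, 100 splits of the same libraries were drawn, with fits of the compared groups alone. In each, 1 of the 100, the real one, gave as many genes, which argues against a chance division of the libraries. The splits cannot tell stage from the enzyme, day of tamoxifen labelling or sequencing batch that changed with it. The real and the highest other counts were 1448 and 145 for tomato-only against double-negative, 900 and 78 for GFP-only against double-negative, 396 and 5 for double-positive against tomato-only, and 960 and 13 for double-positive against GFP-only. For the stages they were 1226 and 286 in double-negative, 899 and 13 in tomato-only and 1086 and 99 in GFP-only cells. For the difference of stage changes they were 379 and 93, in a fit that also held the litter as a block. The main count of 233 came from a fit without that block.

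The splits of the E10.5 libraries (10) and of the dissected embryos (16) are too few for a share under 0.05. In fits of the compared groups alone the real and the highest other counts were 128 and 1 at E10.5, 988 and 1 for region in tomato+ cells, 1155 and 0 for region in tomato- cells, 148 and 0 for the difference of these, and 804 and 2 for tomato+ against tomato- cells.

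Msx1 rose in tomato-only cells from E11.5 to E14.5. The digestion enzyme, partly the read format, the day of tamoxifen labelling and the makeup of the gate changed with stage. The day of labelling cannot be told apart from stage. The enzyme as the whole cause is argued against by the log2 rise of 1.24 from E12.5 to E14.5, both digested with collagenase. The read format as the whole cause is argued against by a log2 rise of 3.35 in the later format alone. That format left litters 27 and 29 at E11.5. If the gate held more distal cells at E14.5, the 100 genes surest to be higher in the autopod would rise more than the 100 surest to be lower there, but their median change differed by -0.48. Both sets came from tomato+ cells of the dissected limbs, which are of another line and had no GFP gate. The members of both sets went both ways, and a requirement added after that value was seen, that both pass camera, was not met (p = 0.774 and p = 0.289 with an estimated correlation), so this explanation stays open. The proximal set rose in double-negative cells (median 1.70, 65 of 100 genes higher) and less in tomato-only cells (median 0.32, 35 higher and 26 lower), with a median difference of -1.60 per gene (camera p = 7.1e-06 with an estimated correlation), so an altered makeup of either gate and a change of Msx1 within cells could both contribute.

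A cluster of 403 cells led by the neutrophil gene S100a8 drew 96.8% of its cells from replicates 7 and 8, with 240 in the E11.5 GFP-only and 83 in the E11.5 double-positive library of replicate 8, gates that would remove neutrophils. Per 1000 UMIs these cells held 1.09 of S100a8, 0.666 of Stfa2 and 0.287 of Lyz2, against 0.0375, 0.0495 and 0.0211 in the other mesenchymal cells of replicate 8. Neutrophils alone in the wells are argued against by Prrx1, a limb mesenchyme gene. Its level was 0.769 times that of the other cells (95% interval 0.696 to 0.849, from pooled UMI counts, counting error only). Free neutrophil RNA spread evenly over the plate may be a source and stays open. The variance of S100a8 UMIs was 3.37 times their mean, against a bound of 3 set beforehand. The 95% bootstrap interval, added after the value was seen, was 2.07 to 4.84 (282 thinned cells of the GFP-only library). No biological explanation was tested.

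Globin UMIs occurred in 46.5% of mesenchymal cells of the double-negative gate and in 0.916% to 2.02% of those in the other gates. The 5% of double-negative cells with most globin held 39.5% of it, between the bounds of 25% for RNA spread evenly over wells and 50% for a few wells with an erythroid cell or part of one. The 2 explanations cannot be told apart with this value, and the erythroid cells themselves, with 126 named in this gate, are not removed by a negative gate.

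Of 64 groups of 4 to 10 values tested for a lone extreme value 3 had one, with 3.2 due to chance. Msx1 stood at 558 CPM in the E13.5 tomato-only library of replicate 26, against 380.1 to 430 CPM in the others. Scx stood at 72.0 CPM in the E11.5 tomato-only library of replicate 29 (others 152.5 to 161.5) and at 19.4 CPM in the E12.5 tomato-only library of replicate 20.1 (others 51.6 to 55.4). Outside the comparisons, 4 wells recorded as empty reached the minimum of UMIs, and the E11.5 tomato-only library of replicate 8 held 150 ectoderm-like cells.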

How the results depend on the processing

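The alternatives without the mitochondrial limit and without the S100a8 cluster were chosen after seeing the data. No count of genes moved by more than 1.5 times under DESeq2, its size factors, 300 or 1000 UMIs per cell, finer clusters, left limbs alone, embryo names shared between litters, or without the S100a8 cluster. With all cells summed the counts were 2383 for tomato-only against double-negative, 1586 for double-positive against GFP-only and 1451 for tomato+ against tomato- in dissected limbs, and without the mitochondrial limit the last was 1366. In the later read format the counts were 224 and 488 for double-positive against tomato-only and GFP-only, 1062, 853 and 1045 for the stage change of double-negative, tomato-only and GFP-only cells, and 98 for the difference of stage changes. With E12.5 for E11.5 the stage counts were 978, 342 and 1090, and with only the groups compared the last 2 gates gave 899 and 1086. At E10.5 the count was 358 without a filter, 15 with the libraries of replicate 22 summed, and 34 to 267 without 1 library. The regional difference gave 85 to 137 genes without 1 embryo and 92 with no replicate block. The cause was not tested.

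With the replicate block (litter) the difference of stage changes rose to 382 genes and the E10.5 comparison to 517. With it 2 named genes no longer passed, and it changed no other of the calls tested, 348 for genes and 113 for lists. Plain stage changes have no value with the block, because a litter has 1 stage. Leaving out 1 litter gave 1349 to 1587, 806 to 942, 331 to 436 and 821 to 1029 genes for the 4 gate comparisons, 1048 to 1402 for the stage change in tomato-only cells, and 169 to 240 for the difference of stage changes.

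The rise of the Msx1 share in double-negative cells missed the threshold after thinning to 2000 UMIs (8.55 points) and without thinning (8.46), and ranged from 11.6 to 15.7 points without 1 litter. Codetection of Msx1 and Col2a1 turned positive in GFP-only cells at 500 UMIs (0.601) and passed in double-positive cells at 2000 UMIs (-0.906). As above, Msx1 values of these gates are not read for direction. Codetection of Msx1 and Scx passed in GFP-only cells at 500 UMIs (-0.513) and without the S100a8 cluster (-0.623), ranged from -0.632 to -0.428 without 1 litter, passing without litter 8 or 28, and passed in double-positive cells at 2000 UMIs (-0.625). Codetection of Sox9 and Scx passed in GFP-only cells without thinning (0.256). The cause was not tested.

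The Msx1 difference of stage changes missed the threshold with only the groups compared (2.01, adjusted p = 0.0595). In 17 values, for 14 results of 12 named genes, the sign changed. With E12.5 for E11.5 these were, in double-negative cells, Msx1 (-0.34) and Grem1 (0.44). In tomato-only cells they were Pcolce2 (-0.27), Bmp2 (-0.95), Bambi (-0.064) and Rrm2 (0.29). In GFP-only cells they were Msx1 (-0.53), Hoxd13 (-0.76), Evx2 (-0.29), Hoxa13 (-0.63), Lyz2 (2.94) and S100a8 (4.08), and in the difference Stk26 (-0.10) and Pcolce2 (-0.19). S100a8 in GFP-only cells ranged from -5.30 to 1.43 without 1 litter, changing sign only without replicate 8, and changed sign in the later format, which leaves that litter out (0.77), and Bambi in tomato-only cells with all cells summed (-0.20). For the rest the cause was not tested.

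In 12 values, for 10 list tests, the direction changed. With all cells summed, which returns the cell types set apart, these were endothelial (camera adjusted p = 2.8e-10) and ectoderm (adjusted p = 9.5e-04) for GFP-only against double-negative, ectoderm for double-positive against tomato-only (adjusted p = 9.2e-14) and for stage in double-negative (adjusted p = 5.2e-05) and tomato-only cells (adjusted p = 5.3e-19), and Schwann for stage in tomato-only cells (adjusted p = 2.8e-07) and its difference (adjusted p = 6.1e-22). Without a filter they were ectoderm for stage in tomato-only cells (adjusted p = 9.2e-04) and Schwann for the difference (adjusted p = 1.4e-04). With E12.5 for E11.5 they were cell cycle in tomato-only (adjusted p = 0.0765) and hedgehog (adjusted p = 0.813) and autopod in GFP-only cells (adjusted p = 0.0095). The cause of the last 5 was not tested. Of the other values, 19801 for genes and 5555 for lists kept their side, 795 and 59 lost the threshold, and 6 and 153 passed it. DESeq2 gives no list tests, and a fit of only the groups compared was not made apart for E10.5, the regional difference and the dissected tomato comparison, whose fits hold no other groups. At these UMI totals and library numbers 30% of simulated 2-fold stage changes in double-negative cells were recovered, so a gene without a call is not shown to be unchanged, and depth was not varied apart from library number.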

Other observations

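In the 4 unsorted E10.5 libraries, 2 plates each of replicates 7 and 10, which enter no comparison, 14.0% ± 1.46 (SD over 4 plates of 2 replicates) of mesenchymal cells held an Msx1 UMI after thinning and 32.1% without it. In dissected tomato+ cells Msx1, cell cycle genes and 9 of 13 limb progenitor genes (3 lower) were higher in the autopod, and cartilage genes in the proximal limb.

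The cells set apart from mesenchyme followed the gates, which can set these numbers. Muscle-like cells numbered 610 in the GFP-only gate, 348 in the double-negative, 12 in the tomato-only and 2 in the double-positive gate. An Scx UMI was found in 15.4% of muscle-like cells after thinning (181 of 1173, exact 95% interval 13.4% to 17.6%, 29.2% without thinning, median 3096 UMIs per cell) and in 0 of 181 erythroid-like cells (exact 95% interval up to 2.02%, median 1961.5 UMIs). Ectoderm-like cells numbered 210 in the tomato-only gate, 205 of them at E11.5, and 61 in the double-negative gate. Schwann-like cells numbered 47 in the tomato-only gate, 46 of them at E11.5, and 81 in the double-negative gate. Erythroid-like (126), macrophage-like (185) and endothelial-like cells (77) lay almost entirely in the double-negative gate, with 2 erythroid-like cells in the tomato-only gate and 1 endothelial-like cell in each of the GFP+ gates.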
